A study of Mus musculus with 3 samples.

How the data were processed

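Mature medullary thymic epithelial cells, the stromal cells of the thymus that present peripheral tissue antigens to developing T cells, were compared between 3 mouse genotypes. Per the series' design text, cells with high MHC class II were sorted from pools of typically 3 mice aged 6 weeks, and amplified RNA was hybridised to Affymetrix Mouse Gene 1-ST arrays. Each genotype had 1 library, so there are no replicates, no p-value is given, and every difference describes 2 libraries and not the conditions. The number of arrays limits the precision of all values.

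The deposited values are probe-set intensities on a linear scale, for which RMA is named per the submitters' processing notes. Its version, software and annotation are not given in the sources used here. Any step that returned the values to a linear scale is not stated either. The values were all positive with medians near 100, so log2 was taken here, as the plan fixed before the data were examined had allowed. No further normalization entered the main values, and the quantiles still differed between libraries.

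Libraries were grouped by title and genotype. The free-text description fields of the AireKO and Sirt1cKO libraries name each other's genotype, so the counts, the overlaps, the list medians and the named genes' differences from WT were also computed with these labels exchanged. No column of values belonged to no sample.

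Of 34760 probe sets, 21640 had 1 gene symbol in the platform annotation, 1321 had several and 11799 had none listed. Probe sets with several symbols were not named. Entrez identifiers of 99.6% of the single-symbol probe sets matched a RefSeq gene table of GRCm38.p6, which changed 0 symbols. Where a gene had several probe sets, the one with the highest mean over the 3 libraries was kept, which gave 19937 genes. A gene was called measured when its highest value reached the median of all values, 6.81 on the log2 scale, which left 12556 genes. A gene was counted as lower or higher at a difference of at least 2-fold.

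Olfactory receptor genes, which are mostly silent outside the nose, served as background, with 1027 of them on the array. A value at or below their 95th percentile in a library was treated as within background. A fold against such a value is given as "at least", with that percentile in place of the dim value. This use of the percentile was added after the data were examined.

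There were 36 gene lists and the union of the 10 tissue lists among them. They cover literature Aire-dependent, Aire-independent and Fezf2-linked antigens, tissue antigens, epithelial and other cell types, and pathways. The median difference of each list was placed among 10000 random lists of the same size, matched in 20 bins of mean brightness. A list was called lower below percentile 2.5 and higher above percentile 97.5, so a call is relative to genes of like brightness and describes these libraries. List medians take all members on the array, many of them within background. For some lists the median over measured members is given too. Medians of measured members with lower bounds were added after the data were examined.

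Named genes followed a rule fixed before the data were examined. It took Aire, Sirt1 and Foxn1, the 8 largest decreases and 8 largest increases in each comparison with WT, and 5 of each between the knockouts. It also took the 5 largest shared decreases and increases, up to 4 members per list, and all members of the lists of Aire-dependent and Aire-independent antigens. Predicted genes, small RNAs, olfactory and vomeronasal receptors and segment genes were counted but not named. Sex-linked, parathyroid, effector T cell, strain-variable and MHC class II genes named beyond the rule were chosen after leading genes had been seen.

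Before the data were examined, the alternatives chosen were quantile normalization, loess against the mean of the 3 libraries with a span of 0.3, centring each library on the median of its measured genes, other brightness filters, other uses of several probe sets, other matching of random lists, and thresholds of 1.5-fold and 3-fold. Removal of X and Y genes, a shift that sets the median difference from WT to 0, and counts that take each fold against background as its lower bound, were added after the data were examined. Chance overlap through the shared WT library was simulated 100 times. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. On simulated data for AireKO minus WT over 19937 genes, the count recovered 56% of genes lowered exactly 2-fold and 100% of genes lowered 4-fold. On simulated data for Sirt1cKO minus WT, 4% of random lists of unchanged genes were called. The simulated noise was independent for each gene, so these values check the code and give no rate of false calls in the real libraries.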

Results

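The series holds 3 libraries of sorted mature medullary thymic epithelial cells. WT came from Sirt1fl/fl mice, Sirt1cKO from Sirt1fl/fl mice with Foxn1-Cre, which deletes in thymic epithelium, and AireKO from Aire-null mice. Aire drives expression of many peripheral tissue antigens in these cells, and Sirt1 is a protein deacetylase. The median intensity was 107.8 in WT, 116.4 in AireKO and 111.2 in Sirt1cKO. The 95th percentile of olfactory receptor genes lay at log2 6.02, 6.89 and 6.34 in the same order, so dim genes were least resolved in AireKO. Across measured genes, which are not independent replicates, r was 0.95 between WT and Sirt1cKO, 0.93 between the knockouts and 0.87 between WT and AireKO.

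The targeted genes did not identify the knockouts. Aire had a log2 intensity of 11.97 in WT, 11.55 in the library labelled AireKO and 11.24 in the library labelled Sirt1cKO. Sirt1 stood at 11.40, 11.42 and 11.27, and Foxn1, the transcription factor of thymic epithelial identity, at 10.47, 9.43 and 9.99. Whole-transcript probe sets need not lie in the deleted part, so these values check neither label. Aire was lowest in the library labelled Sirt1cKO, and the description fields conflict with the titles. AireKO and Sirt1cKO therefore stand throughout for the library labelled so by its title, and every direction drawn rests on that label.

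The libraries also differed in sex-linked genes, and the labels give no sex. Xist, the RNA of the inactive X chromosome, stood at 12.17 in WT, 6.75 in AireKO, within background, and 11.46 in Sirt1cKO. The Y-linked gene Eif2s3y stood at 4.23, within background, in WT, 9.75 in AireKO and 8.92 in Sirt1cKO. Uty stood at 4.78, 8.87 and 8.43, and Kdm5d at 5.12, 7.80 and 7.60. Sry, also Y-linked, stood above background in all 3 libraries, at 7.49, 7.86 and 7.92, while Zfy1 and Usp9y were within background in all 3. WT thus showed Xist with Eif2s3y, Uty and Kdm5d within background, AireKO showed the reverse, and Sirt1cKO showed both kinds of signal. Genotype therefore cannot be told apart from this sex-linked difference in either comparison with WT, most fully in AireKO. H2-Ea, an MHC class II gene with a defective promoter in the labelled strain, was bright in AireKO alone, at 13.23. A different genetic background was not excluded, so it too may enter any difference between AireKO and the other libraries.

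**Figure D1:**
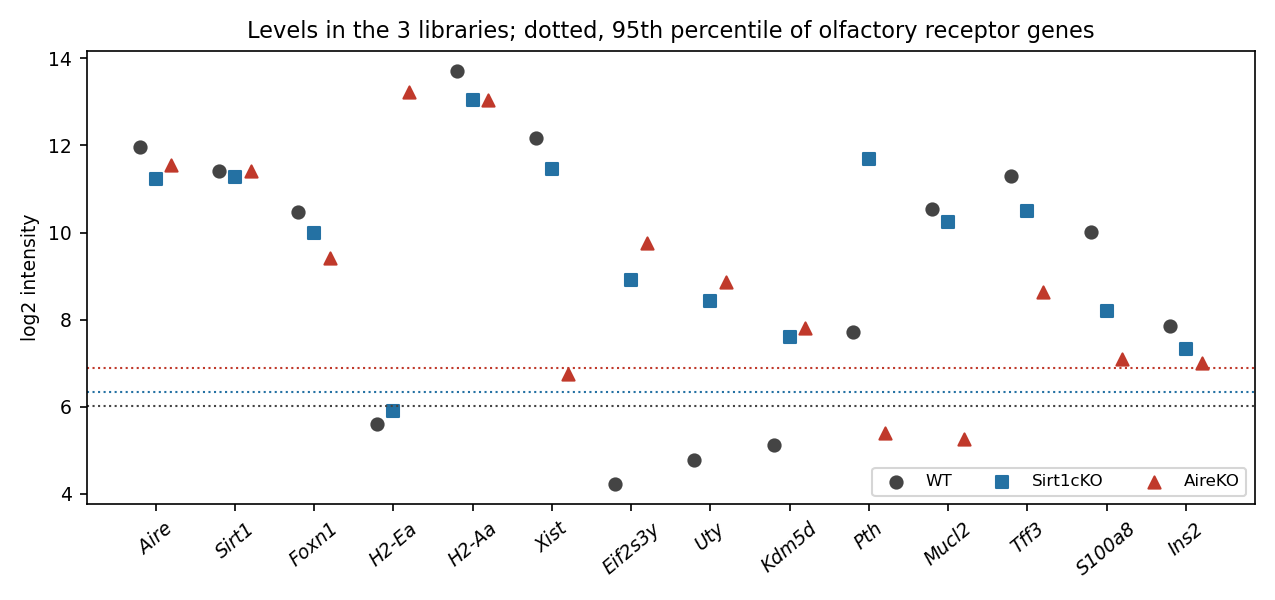
Log2 intensity (vertical axis) of 14 genes in the WT, Sirt1cKO and AireKO libraries, 1 point per library, with dotted lines at the 95th percentile of olfactory receptor genes. H2-Ea stands at 13.23 in AireKO and within background in the other libraries.

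The first comparison asked how loss of Aire altered these cells. Relative to genes of like brightness, the 10 tissue lists together were called lower in the library labelled AireKO. Not every list went that way. The testis list, at 0.34 over all members, was not called. Its 10 measured members were called higher, at 0.52 by lower bounds. The filter takes a gene on its highest library, and the 62 measured olfactory receptor genes stood higher too, at 1.13. No increase of testis genes is therefore read from that call. The largest decreases, named next, are not all tissue antigens. The mucin-like gene Mucl2 was at least 12.5-fold lower, the tachykinin precursor Tac2 at least 11.3-fold lower, and Ltf, which encodes lactoferrin, at least 9.58-fold lower than in WT. Ly6a2 was at least 12.7-fold lower, Ly6g, a neutrophil surface gene, at least 16.9-fold lower, and the odorant-binding gene Obp2a at least 2.91-fold lower. Crabp1, a retinoic acid binding protein, differed by -3.99 on the log2 scale, and Xist was at least 38.9-fold lower.

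Of measured genes, 1062 were at least 2-fold lower and 336 at least 2-fold higher in AireKO than in WT. The median difference of all measured genes was -0.19. The split depended on scaling, with 845 lower and 412 higher after quantile normalization, 776 and 430 after loess, 661 and 595 with the median difference set to 0, and 543 and 759 after median centring. With folds against background counted as lower bounds, 922 were lower and 306 higher. Median centring moved the differences of all genes by 0.27 in AireKO minus WT, 0.10 in Sirt1cKO minus WT and -0.17 between the knockouts.

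The largest value on the higher side was H2-Ea, an MHC class II alpha chain gene, at least 148.3-fold higher in AireKO. Il4, a T helper cytokine, differed by 3.71, Ccnb1ip1, a meiotic recombination gene, by 3.35, and Epyc, a cartilage proteoglycan gene, by 3.12. Zfp979 was at least 2.96-fold higher. The Y-linked genes Eif2s3y, Srsy and Uty were at least 13.3-fold, 33.2-fold and 7.23-fold higher.

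The literature list of Aire-dependent antigens had a median difference of -0.60 over 13 genes, at percentile 0.145 of matched lists. That median falls on a gene within background in AireKO. Over the 8 measured members the median was -1.66, again called lower, and -1.57 with folds against background as lower bounds. Of its 8 measured members, 4 were at least 2-fold lower: Bpifb1 at least 4.87-fold, and S100a8, Tff3 and Ppy with differences of -2.91, -2.65 and -2.48. Ins2, which encodes insulin, differed by -0.85 and Pcp4 by -0.84, while Csn2 differed by 0.50 and Fabp9 by 0.96. Svs2 and Muc6 were within background in both knockouts, and no exact difference is given for them. The list of 5 Aire-independent antigens had a median of 0.15 and was not called, although its casein member Csn1s1 was at least 2.31-fold lower.

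Over all 10 tissue lists together, 310 genes were on the array and 177 were measured. In AireKO, 64 were at least 2-fold lower and 6 higher, or 48 and 6 with folds against background as lower bounds. Their median difference was -0.12, below all matched random lists, and it became -0.29 after loess and 0.15 after median centring with the call kept. Over the measured members it was -0.71, or -0.46 with lower bounds. Stomach and intestine genes had a median of -0.97, and 18 of 31 measured members were at least 2-fold lower, 14 of them by lower bounds. They included pepsinogen C, Pgc, at least 5.01-fold, Muc5ac, at least 5.57-fold, and the gut peptide Nts, at least 3.19-fold lower. Pancreas genes had a median of -0.63, with the chymotrypsinogen gene Ctrb1 at -2.66 and Reg3b at least 3.15-fold lower. Skin genes had a median of -0.60, with Asprv1 at -2.20 and Krt1 at -2.04. Liver genes had a median of -0.35, -0.56 after loess and -0.07 after median centring, with Alb at least 4.01-fold lower and Saa2 at least 3.70-fold lower. The salivary, lacrimal and mammary list had a median of -0.28, -0.38 after loess and -0.01 after median centring, with Bpifa1 at -3.12. Its call was lost under 2 of 8 alternatives. Major urinary proteins and lipocalins, with 4 of 13 members measured, were called lower at -0.09, which became -0.43 after loess and 0.18 after median centring, and lost the call against unmatched random lists. With lower bounds, the measured members had medians of -0.78 for stomach and intestine, -0.81 for pancreas, -0.69 for skin, -0.38 for liver, -1.09 for salivary and -0.22 for urinary proteins, the last no longer called. Prostate genes had 0 measured members and a median intensity within background in all 3 libraries, so nothing is read from their median of 0.04, -0.29 after loess, or its call.

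Epithelial identity genes and several pathways were lower in the same library. Mature medullary genes had a median of -0.58, with the chemokine Ccl22 at -1.58 and the tight-junction gene Cldn4 at -1.23. The list of post-Aire and mimetic cells had a median of -0.42, with the microfold cell gene Gp2 at -1.81. Interferon response genes had a median of -0.62, with Irf7 at -2.03, and oxidative phosphorylation genes -0.58, with Atp5a1 at -1.47. Immediate early and heat shock genes had a median of -0.52, with Dusp1 at -1.43. Neutrophil genes had a median of -0.48, with 5 of 9 measured members at least 2-fold lower and a median of -1.36 over measured members with lower bounds, and thymocyte genes had a median of 0.24 and were called higher, a call lost under 3 of 8 alternatives. Against random lists matched on WT brightness alone, the calls of the mature medullary, oxidative phosphorylation and immediate early lists were lost.

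**Figure D2:**
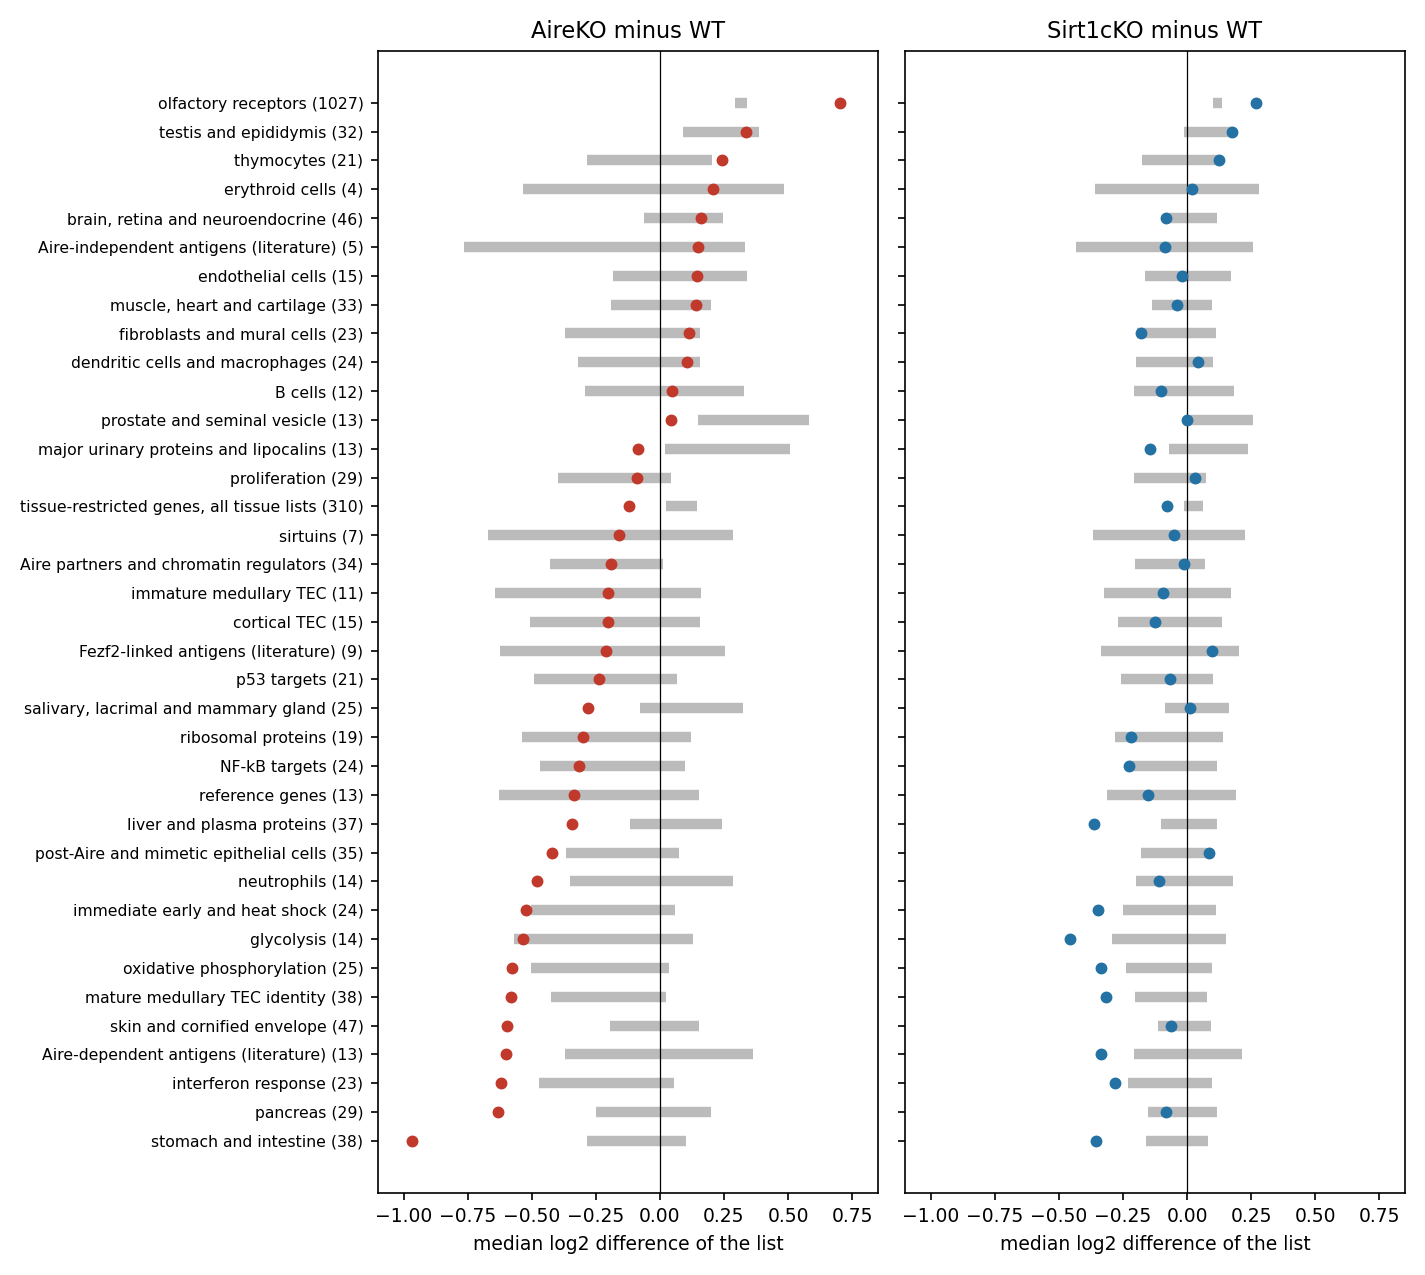
Median log2 difference from WT (horizontal axis) of each gene list, with its number of genes on the array, in AireKO and Sirt1cKO. Grey bars span the range of matched random lists outside which a list was called, and the stomach and intestine list lies at -0.97 in AireKO and -0.36 in Sirt1cKO.

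The second comparison asked how loss of Sirt1 in thymic epithelium altered the cells. The library labelled Sirt1cKO differed less from WT, with 211 measured genes at least 2-fold lower and 101 higher. Gpx3, a secreted glutathione peroxidase, differed by -2.54, the translation factor gene Eif5a by -2.14 and the ATP synthase subunit gene Atp5d by -2.11. Prg2 and Rnase2a, which encode eosinophil granule proteins, differed by -1.96 and -1.90, Ctrb1 by -1.93 and Crabp1 by -1.89. Gsdmc2, a gasdermin gene, was at least 2.70-fold lower.

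On the higher side, the parathyroid hormone gene Pth stood at 11.70 in Sirt1cKO and 7.72 in WT, a difference of 3.98. The Y-linked genes Eif2s3y, Uty, Srsy and Kdm5d were at least 7.46-fold, 5.33-fold, 8.47-fold and 2.99-fold higher. The bitter taste receptor gene Tas2r118 differed by 2.25, Raet1d, a ligand gene of the NKG2D receptor, was at least 2.14-fold higher, and the sodium channel gene Scn2a at least 2.88-fold higher. After quantile normalization the counts were 173 lower and 103 higher, after loess 192 and 114, with the median difference set to 0 163 and 123, and after median centring 146 and 142.

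Aire-dependent antigens had a median difference of -0.33 in Sirt1cKO, at percentile 0.2 of matched lists. That value belongs to a gene within background in all 3 libraries, and the 8 measured members had a median of -0.52, also called lower. S100a8, at -1.82, is also on the neutrophil list, of which 3 of 9 measured members were at least 2-fold lower, with Ly6g at -1.34 and Mpo at -1.13. Over its 9 measured members the neutrophil list had a median of -0.78 and was called lower, while over all members it was not. Among the 8 Aire-dependent members S100a8 was the 1 at least 2-fold lower, with Tff3 at -0.80, Pcp4 at -0.77, Ppy at -0.52, Ins2 at -0.51 and Bpifb1 at 0.14. The Aire-independent list had a median of -0.09 and was not called. Of the 177 measured tissue genes, 23 were at least 2-fold lower and 2 higher, or 19 and 2 by lower bounds. Their median was -0.08, below all matched random lists, and became -0.12 after loess and 0.02 after median centring with the call kept. Over the measured members it was -0.25.

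Liver genes had a median of -0.36 in Sirt1cKO, with Alb at -1.34, and stomach and intestine genes -0.36, with Nts at -1.77 and Pgc at -1.42. Over measured members these medians were -0.41 and -0.49. The brain, retina and neuroendocrine list, at -0.08, was called lower, with Calb2 at -1.60, a call lost under 2 of 8 alternatives. Its median was -0.14 after loess and 0.02 after median centring, and -0.29 over its 24 measured members, again called lower. Major urinary proteins and lipocalins, at -0.14, were also called lower, but not against unmatched random lists. Their median was -0.28 after loess and -0.05 after median centring. Over the 4 of 13 members that were measured it was -0.62, or -0.52 with lower bounds. Nothing is read from the median of -0.00 for prostate genes, 0.10 after median centring, which lay within background. Pancreas, skin and salivary lists, with medians of -0.08, -0.06 and 0.01, were not called, although 7 of 21 measured pancreas genes were at least 2-fold lower, 6 by lower bounds. Over measured members the medians were -0.14, -0.22 and -0.46, and the salivary list was then called lower.

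Mature medullary genes had a median of -0.31, with the protease gene Ctss at -0.81. Glycolysis genes had a median of -0.46, with Ldha at -0.91, oxidative phosphorylation genes -0.33, immediate early and heat shock genes -0.35, and interferon response genes -0.28, all called lower. NF-kB targets, at -0.23, were called lower, a call lost under 6 of 8 alternatives. The list of post-Aire and mimetic cells, at 0.09, and thymocyte genes, at 0.12, or 0.26 over measured members, were called higher. Each call was lost or reversed under 2 of 8 alternatives. The interferon and immediate early calls were lost against random lists matched on WT brightness alone. The mimetic list was mixed, with 15 of 35 members below 0, the tuft cell genes Gnat3 at 0.77 and Dclk1 at 0.68, and Tagln at -0.72.

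The knockouts were also set against each other and against WT together. Of the 211 genes lower in Sirt1cKO, 173, or 82.0%, were lower in AireKO too, and 67 of the 101 higher genes, or 66.3%, were higher in AireKO too. Shared decreases were led by Gpx3, Eif5a, Atp5d, Ctrb1 and Crabp1. Shared increases were led by the Y-linked genes Eif2s3y, Uty, Srsy and Kdm5d, which follow the sex-linked difference, and by Raet1d. Counted as lower bounds, 189 genes were lower and 93 higher in Sirt1cKO, with 144 and 58 shared. Pth was the 1 gene counted as lower in AireKO and higher in Sirt1cKO, and 0 genes went the other way. It was within background in AireKO and at least 1.78-fold lower there than in WT, so a 2-fold decrease was not established. Of the 1062 genes lower in AireKO, 1009, or 95%, were below WT in Sirt1cKO, against 58.4% of all measured genes. Their median was -0.60 there and -1.28 in AireKO.

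Both comparisons use the same WT library. Independent lists would share 17.8 lower and 2.7 higher genes. Unchanged libraries of equal spread shared 29.9 lower and 29.9 higher genes on average, and libraries with all of Sirt1cKO minus WT drawn from WT noise shared 104.3 and 101.9. The correlation of the differences across genes was 0.70, against 0.50 and 0.65 in these simulations, and the covariance was 0.18, against 0.08 and 0.16. These simulated correlations and covariances are set by the library variances put in, so they serve as reference values and not as tests. Of simulated genes lower in AireKO, 88.3% and 89.9% were below WT in Sirt1cKO on average and at most 94.4% and 92.8%, with mean medians of -0.60 and -0.52. The observed 95% lay above both, and the observed median within the first range but below the second, which ended at -0.56. The 173 shared lower genes exceeded the highest runs, 41 and 125. The 67 shared higher genes exceeded the highest equal-spread run, 42, but lay under the lowest WT-noise run, 85, and the 102 after median centring lay inside that range. The runs were not repeated for centred values. The simulations treat genes as independent, so their ranges are too narrow if genes vary together. They also gave shorter lists, on average 128.2 and 590.1 genes lower in AireKO, against 1062 observed. In Sirt1cKO 126.8 and 146.8 were lower, against 211. They carried no offset, while the observed median differences were -0.19 in AireKO and -0.07 in Sirt1cKO. The offset also varied with brightness, which the simulations left out. With all genes in 10 bins of brightness, the AireKO median was 0.35 in bin 1, the dimmest, and -0.30 in bin 9. The Sirt1cKO median was 0.14 and -0.09 in the same bins. List size and offset can raise the observed overlap and the observed 95%, so an excess over the simulations does not by itself show a shared effect.

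**Figure D3:**
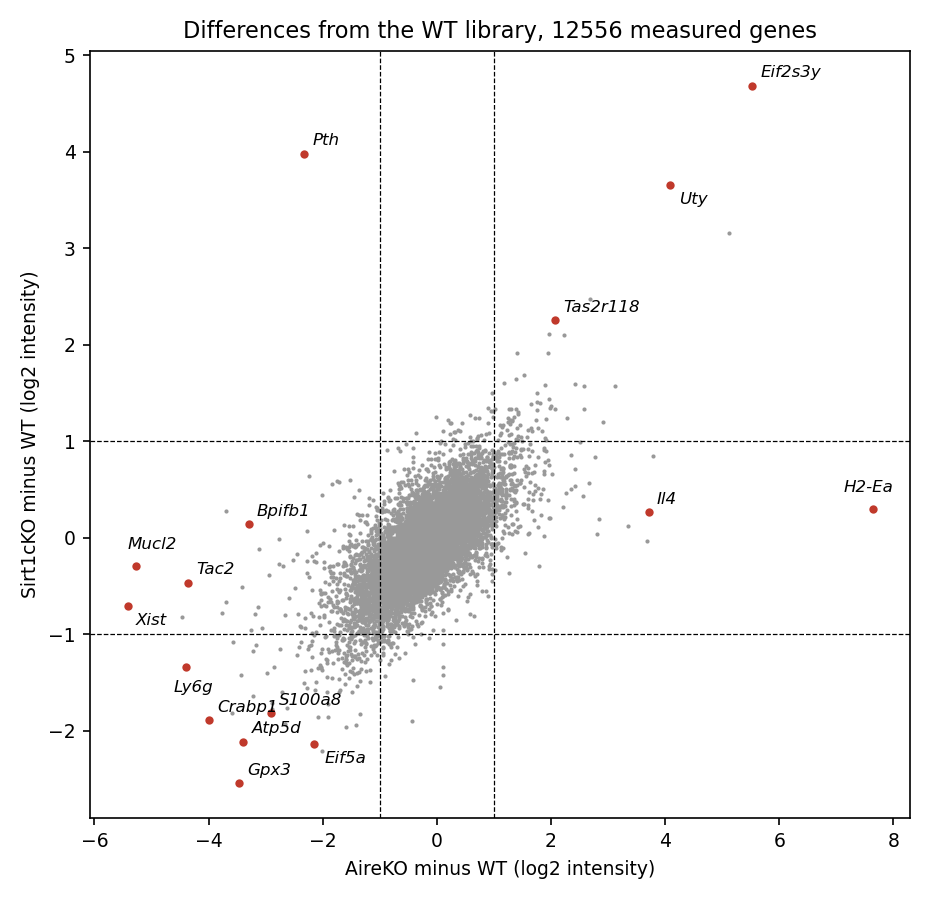
Log2 difference from WT of each of 12556 measured genes in AireKO (horizontal axis) and Sirt1cKO (vertical axis), 1 point per gene, with dashed lines at 2-fold. The correlation across genes is 0.70, and Pth lies at 3.98 in Sirt1cKO and within background in AireKO.

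Directly compared, 341 genes were at least 2-fold higher and 131 lower in Sirt1cKO than in AireKO. Pth was at least 28.0-fold, Mucl2 at least 10.2-fold, Xist at least 23.9-fold and Tac2 at least 8.19-fold higher, and the surface antigen gene Psca differed by 3.97. H2-Ea was at least 118.5-fold, Zfp979 at least 2.36-fold and Ccnb1ip1 at least 8.99-fold lower, with Il4 at -3.44 and the thioesterase gene Acot12 at -2.76. Quantile normalization gave 331 higher and 152 lower genes, loess 279 and 141, the median difference set to 0 258 and 193, median centring 209 and 242, and lower bounds 278 and 111.

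Stomach and intestine genes had a median of 0.50 in this comparison, mimetic cell genes 0.46, interferon response genes 0.54, neutrophil genes 0.51 and skin genes 0.33, all called higher. Salivary, lacrimal and mammary genes, at 0.17, were called higher, with a median of 0.39 after loess and -0.00 after median centring, but not over measured members with lower bounds, at 0.20. Fibroblast and mural genes, at -0.24, were called lower, as were olfactory receptor genes, at -0.43, the list used as background. Aire-dependent antigens had a median of 0.13, at percentile 84.7, and -0.04 after median centring, and were not called. That value belongs to a gene within background in both knockouts. After loess the list was called higher at 0.27, and over its 8 measured members at 0.71. The 10 tissue lists together had a median of 0.02, at percentile 99.98, with 32 genes higher and 1 lower. That median was 0.12 after loess and -0.16 after median centring with the call kept, and lost its call against unmatched random lists. With lower bounds, the measured members had a median of 0.13.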

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

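The tests of the shared decreases, of the stomach and intestine list, of the other MHC class II genes and of strain-variable genes and unlisted probe sets under other settings were chosen after their results were seen. Probe sets without a listed gene lay outside all comparisons, and more of them stood above WT than below. Of 4896 measured, 888 were at least 2-fold higher in AireKO than in WT and 465 lower, and 375 were at least 2-fold higher in Sirt1cKO and 177 lower. Background rose too. All olfactory receptor genes, unfiltered, had medians of 0.70 in AireKO and 0.27 in Sirt1cKO, and the 62 measured ones 1.13 and 0.40. These probe sets, past the brightness filter, had medians of 0.23 and 0.13. After quantile normalization, all olfactory receptor genes had 0.39 and 0.13, against 0.27 and 0.14 for the probe sets. After loess the values were 0.40 and 0.16 against 0.28 and 0.15. Counts in AireKO were 945 higher and 418 lower after quantile normalization, 1439 and 294 after median centring, and 808 and 351 by lower bounds, and in Sirt1cKO 364 and 153, 486 and 127, and 312 and 154. With no gene listed, no source was tested for them.

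Of measured genes, 173 were at least 2-fold lower in both knockouts. RNA of the AireKO library mixed into Sirt1cKO is argued against, because H2-Ea in Sirt1cKO lay within background, at most 0.844% of its intensity in AireKO. Chance values of the shared WT library cannot be told apart for the overlap. The 173 exceeded the highest of 100 simulations, 125, as did 137 after quantile normalization and 153 after loess. The 122 with the median difference set to 0 and the 107 after median centring did not. The simulations used the variances of the main values and were not rerun for these settings. Independent noise in 3 libraries cannot be told apart either: it has an expected covariance of Sirt1cKO minus AireKO with Sirt1cKO minus WT of 0 or more, and -0.0208 was found, but the bootstrap standard error of 0.003 treats genes as independent and no replicate gives the spread of noise that moves genes together. The covariance of -0.0208 restates the gap between the observed covariance of the differences from WT and that of the WT-noise simulation. It is therefore not a separate test. A technical axis common to the libraries, their sex-linked difference and the untested effect of both genotypes on the same genes all stay open.

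Stomach and intestine genes were lower in AireKO than in WT. Chance values of the WT library are argued against as the whole cause, since with WT left out their median differed by 0.496 between the knockouts, and by 0.32 after median centring, with the call kept. The list had the lowest median of all lists in AireKO minus WT, and both comparisons use the AireKO library. Chance values of the AireKO library therefore stay open.

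H2-Ea was bright in the library labelled AireKO alone, although C57BL/6 mice, the labelled strain, carry a defective H2-Ea promoter. A brightness or normalization shift is argued against by the other 7 MHC class II genes, whose median difference was -0.65. A genetic background other than C57BL/6 cannot be told apart by a count that ignores direction, since 2 of 8 other strain-variable genes, Nnt at -1.13 and Entpd4 at -1.02, differed by at least 2-fold in AireKO and 0 in Sirt1cKO. The plan had asked for 3 such genes or none, and 1 was counted after quantile normalization or loess and 0 after median centring or with the median difference set to 0. Of the 8, Gbp2b, Wdfy1 and Thumpd1 did not reach the brightness filter, so fewer genes could inform the count. Lower Nnt does not speak for another strain, since C57BL/6J itself carries the Nnt deletion, and loss of Aire, a mislabelled library and cells of another strain were not tested.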

How the results depend on the processing

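Removal of X and Y genes, the shift of the median difference to 0 and the use of lower bounds for folds against background, in counts and in medians of measured list members, were chosen after the data were examined. The correlation of the differences stayed within 0.1 of its main value in all settings run. Loess, quantile normalization, the mean of probe sets, every probe set on its own, removal of X and Y genes and lower bounds kept all counts within 1.5 times. No paired analysis was possible because each genotype has 1 library, and leave-one-out fits were not possible for the same reason. In AireKO, the plan held that a brightness-dependent shift would take the lower count under the higher one or to less than 50% of 1062. Loess left 776 lower and 430 higher, which by that rule argues against the shift as the whole cause of the excess. However, loess was fitted to all probe sets and left measured genes with a median difference of -0.08. The counts after loess therefore cannot exclude a remaining shift of the measured genes. Median centring, tested after the split was seen, gave 543 lower and 759 higher, but it moved the median difference from -0.19 to 0.11. Setting that median to 0 gave 661 lower and 595 higher, so how far the excess comes from the centre cannot be told apart from a true excess.

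Median centring also gave 242 lower and 209 higher genes in Sirt1cKO minus AireKO, and 107 lower and 102 higher in both knockouts. At 1.5-fold, the counts were 1038 and 504 in Sirt1cKO, 2957 and 1070 in AireKO, 571 and 1484 between the knockouts, and 879 and 307 in both. At 3-fold they were 23 and 14, 233 and 93, 26 and 65, and 19 and 9. Thresholds move counts by construction. Without a brightness filter, 638 genes were higher in AireKO and 200 lower in Sirt1cKO than in AireKO, and with the filter at the 75th percentile 186 and 79, as fewer genes entered. For Aire-dependent antigens, Sirt1cKO minus AireKO was called higher at 0.29 after quantile normalization, 0.27 after loess and 0.71 past the brightness filter, and the cause was not tested. The tissue union kept its median of 0.0178 in that comparison but lost the call against unmatched random lists. The prostate list has no measured member, so it gave no value past the filter.

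With the labels exchanged, each library takes the other's values by construction. The neutrophil, pancreas, skin and salivary calls in AireKO and the glycolysis, NF-kB and brain calls in Sirt1cKO were then lost. Counts became 1062 and 336 in Sirt1cKO, 211 and 101 in AireKO, and 341 lower and 131 higher between the knockouts. The tissue union became -0.0178 in Sirt1cKO minus AireKO, and the mimetic list -0.42 in Sirt1cKO and 0.0853 in AireKO. Pth became -2.32 in Sirt1cKO, against a value within background, and in AireKO Zfp979 became -0.0357, between values within background, Bpifb1 0.14, Lce1a1 0.13, Gp2 0.0853 and Il17rb 0.16. Signal over background limits dim genes most in AireKO, where olfactory receptor genes had a median of 5.37 against 4.58 in WT and 4.90 in Sirt1cKO.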

Other observations

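The remaining lists had these medians. In AireKO and Sirt1cKO they were -0.21 and 0.10 for Fezf2-linked antigens, 0.34 and 0.17 for testis, 0.14 and -0.04 for muscle, and -0.19 and -0.01 for Aire partners, none of them called. The testis list was called higher under 2 of 8 alternatives in AireKO and 4 of 8 in Sirt1cKO. Over its 10 measured members the medians were 0.52, by lower bounds, and 0.42, both called higher. Measured olfactory receptor genes were called higher in both libraries too, so no increase of testis genes is read from these calls. The medians were -0.16 and -0.05 for sirtuins, -0.20 and -0.09 for immature medullary cells, -0.20 and -0.12 for cortical cells, 0.11 and 0.04 for dendritic cells and macrophages, and 0.05 and -0.10 for B cells, also not called. Endothelial genes had 0.15 and -0.02, erythroid genes 0.21 and 0.02, proliferation genes -0.09 and 0.03, p53 targets -0.24 and -0.07, ribosomal proteins -0.30 and -0.22, and reference genes -0.33 and -0.15, with no call. Against WT, fibroblast genes at 0.11 and -0.18 were not called, nor were glycolysis genes at -0.53, NF-kB targets at -0.32 and brain genes at 0.16 in AireKO, nor neutrophil genes at -0.11 in Sirt1cKO. Some of these were called lower under other choices: glycolysis in AireKO under 3 of 8, brain and NF-kB in AireKO and neutrophil in Sirt1cKO under 2 each, and fibroblast genes in Sirt1cKO and ribosomal proteins in both under 1 each. With lower bounds, measured brain genes in AireKO were called lower at -0.42 and muscle genes higher at 0.12. Olfactory receptor genes, at 0.70 and 0.27, were called higher in both. Within uncalled lists single genes stood apart in AireKO, with Fabp7 at 1.68, Maoa at 1.33, the matrix genes Sparc at -2.25, Dcn at 1.90 and Postn at 1.60, and the synaptic gene Snap25 at 1.88.

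T cell effector genes were chosen after Il4, Il10, Ifng and Ctla4 had been seen. In AireKO, Il4 differed by 3.71, Ctla4 by 2.56, Ifng by 1.79, Il2 by 1.02, Il10 by 0.96, Icos by 0.57, Il13 by 0.26, Tnf by -0.39, and Tnfrsf4 by -0.19, which turned to 0.08 after median centring. Il5 was at least 1.79-fold lower. Cd40lg, Il17a and Il21 were within background in all 3 libraries, and Foxp3, Gzmb and Pdcd1 in AireKO, so no difference is given for them. Among neutrophil genes, Ly6g, Ltf, S100a8, Ngp and Mpo were at least 2-fold lower in AireKO, while the receptors Cxcr2 and Csf3r were within background in all 3 libraries.

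Pth was 15.8-fold higher in Sirt1cKO than in WT, and parathyroid cells in the sorted pool are a candidate source, although the sort for EpCAM and MHC class II should limit them. The test, written before its values were seen, asked whether Gcm2, Casr or Chga exceeded both other libraries. The largest such excess was 0.42, for Chga, under the bound of 0.5 that the plan had set as counting against parathyroid cells. That bound was judged unsuitable only after the values were seen, since Casr and Chga already stood at 8.68 and 10.02 in WT, which would hide a small share, and Gcm2 was not among the named probe sets. Parathyroid cells and expression of Pth within the epithelium therefore cannot be told apart here.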
